A study of Saccharomyces cerevisiae S288C with 6 samples.

How the data were processed

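The series holds 6 Agilent 2-colour yeast gene expression arrays of *Saccharomyces cerevisiae* S288C-derived strains, with RNA from wild-type cells (WT) and from cells with the HOG1 gene deleted (hog1). Per the labels, cells were grown for 4 h in air in rich medium (YPD) to mid-log. Hypoxic cultures were then diluted and grown for another 5 h under 100% nitrogen, again to mid-log, so that dilution and culture time differ together with oxygen. RNA was extracted with hot phenol and labelled with the Agilent Quick-Amp kit. Cy5 carried the sample, which was WT hypoxia on 2 arrays, hog1 aerobic on 2 arrays and hog1 hypoxia on 2 arrays. Cy3 carried WT aerobic RNA on all 6 arrays. In the mutant, per the labels, the LEU2 gene stands in place of HOG1, and both strains carry leu2, ura3, his3 and lys2 mutations. The labels state 2 biological replicates for each strain and condition.

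The arrays were read with Agilent Feature Extraction 9.5.3.1. Per the file headers, the mean spot signals and the local background signals are intensity values per channel, not normalized, and the processed signals are intensity values after background subtraction and dye normalization within the array. The deposited log ratio of each spot is log10 of the Cy5 over the Cy3 processed signal, per the file headers. The deposited series matrix holds log2 values of Cy5 over Cy3, as its values show: they correlate with each array's own log ratios at r = 0.9937 to 0.9995, with medians between -0.04 and 0. Other columns used, per the file headers, are flags for each spot (control, well above background, saturated, outlier).

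The mean spot signals and local backgrounds were used, so that the dye normalization could be chosen. Each array has 15744 spots, of which 536 control spots were left out. The other 15208 spots belong to 6256 probes, 3560 with 2 spots and 2696 with 3 spots, and each gene has a single probe. Background was corrected with the normexp method (offset 50), and log2(Cy5/Cy3) was normalized within each array by loess, with limma 3.58.1 in R 4.3.3. Spots that the scanner software had marked as outliers in either channel were left out, 1.75% to 2.28% of spots per array, and no spot was saturated. Spots of a probe were averaged on the log2 ratio. A probe was tested if it was well above background in either channel on at least 2 of the 6 arrays: 6239 probes were tested, 15 were too dim, and 2 had no usable spot on some array. Locus tags were matched to gene symbols of the R64 reference table for 5756 of the 6256 probes, and the other probes keep the names given in the files.

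All 6 arrays were fitted in a single limma model with a mean for each of the 3 groups and moderated variances (3 residual degrees of freedom, 2.73 prior degrees of freedom). Tests are two-sided, and p values were adjusted by the Benjamini-Hochberg method over the 6239 genes, with a threshold of 0.05. The 5 comparisons were WT hypoxia against WT aerobic, hog1 aerobic against WT aerobic, hog1 hypoxia against hog1 aerobic, hog1 hypoxia against WT hypoxia, and the difference of the hypoxia effect between the strains. The first pair of comparisons tests a mean ratio against 0, since WT aerobic RNA is the Cy3 reference and was never in Cy5. The spread of the reference between arrays is part of these ratios, and whether each array had a separate WT aerobic RNA is not stated. No dye swap was made, so a dye bias of a gene stays in both, and stays once in the difference of the hypoxia effects. It cancels in hog1 hypoxia against hog1 aerobic and in hog1 hypoxia against WT hypoxia, where both RNAs were in Cy5. Values are given as log2 ± standard error of this limma fit unless stated otherwise, from 2 arrays per group. The number of arrays limits the precision.

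The replicate numbers of the labels were examined as a pairing. After the group means were taken out, the log2 ratios of arrays with the same number correlated across genes at r = 0.452, 0.750 and 0.567 for the 3 pairs of groups, the Cy3 signals at 0.701, 0.614 and 0.864, and the Cy5 signals at 0.0632, 0.0869 and 0.142. The arrays therefore share a deviation in the reference channel by number. All 6 arrays lie on 1 slide read in 1 scan, with the replicate number as the row and the group as the column, so that number and row cannot be told apart. A fit with the replicate number as a block is given beside the results, called the replicate block or the blocked fit. It has 2 residual and 4.94 prior degrees of freedom. The block takes the shared deviation of the reference out of the residual spread. The error of the mean reference stays in both comparisons against WT aerobic and in the difference of the hypoxia effects. In those comparisons the blocked standard errors and p values leave this error out and can be too small. The fit without the block treats the shared deviation as independent between arrays in its 3 residual degrees of freedom. Its p values in those comparisons can therefore be too small as well.

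Before the data were examined, 26 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. Lists were tested with limma's camera, with a preset correlation between genes of 0.01 and again with a correlation estimated from the arrays, and adjusted over the 26 lists in each comparison. Counts of list members are given over all genes tested and "adjusted over the list alone". The rule names the 10 largest rises and the 10 largest falls past the threshold whose replicates have the same sign, up to 4 members of each list with the largest change past the threshold (or the largest member as a value where none passed), and HOG1, LEU2, URA3, HIS3 and LYS2. Genes past the threshold with the replicate block alone are named where they differ at least 2-fold (log2 of 1) with the same sign in both replicates, and for list members as values. Probes of near-identical genes (PAU, DAN/TIR, HXT and pairs of ribosomal protein genes) may cross-hybridise. Among the PAU probes, 19 share at least 48 of 60 bases with another PAU probe, 7 of them all 60. Counts of PAU genes are therefore not counts of separate measurements in any comparison. The DAN/TIR and PAU lists share 2 genes, named PAU23 and PAU24 in R64. The lists of phosphate starvation genes, Gcn4 targets and mitochondrial ribosomal proteins, the Leu3 targets and the isoform pairs were chosen after seeing the data.

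The procedure was tested on simulated data: 20 data sets for each comparison, with 200 of 6239 genes changed. Genes were drawn as independent, with variances from the blocked fit. The arrays' own replicate deviations were added in the form that the block removes. At a change of log2 2, the fit recovered 95.7% of the changed genes for WT hypoxia against WT aerobic, 96.3% for hog1 aerobic against WT aerobic, 85.4% for hog1 hypoxia against hog1 aerobic, 85.2% for hog1 hypoxia against WT hypoxia and 68% for the difference of the hypoxia effects. At a change of log2 1, the shares were 69.6%, 69.6%, 18.2%, 18.7% and 1.25%. False calls made up 0.216% to 0.36% of the calls, and 4.57% to 5.01% with the replicate block, which recovered 97.2%, 96.6%, 85.3%, 85.2% and 59.1% at log2 1. The blocked shares follow from data built in the form of the blocked fit and are no independent check of it. The added replicate deviations cancel in each group mean, and no dye bias or error of the mean reference was simulated. The shares of both fits therefore do not cover these errors, which stay in the comparisons against WT aerobic and in the difference of the hypoxia effects. A list of 24 random genes shifted by log2 1 was called by camera with the preset correlation in all 20 data sets of each comparison. With the estimated correlation it was called in 20, 20, 19, 20 and 18 data sets. Since the simulated genes were independent, this does not cover lists of correlated genes, such as the PAU genes (estimated correlation 0.897).

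The alternatives were no background correction, normexp offset 10, the Feature Extraction log ratios, median centring in place of loess, scale normalization between arrays, no filter on dim probes, a stricter filter, outlier spots kept, eBayes with trend and robust, the series matrix values, the replicate block, leaving out each array in turn, a 2-fold size threshold, calls of the same sign on all 6 arrays, and WT hypoxia against hog1 aerobic with both in Cy5. The Cy5 channel alone and the replicate block combined with the Feature Extraction log ratios or with median centring were chosen after seeing the data. A left-out array leaves its group with 1 array, which is assumed to vary like the other groups.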

Results

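Gene expression was measured on 6 two-colour Agilent arrays, 2 for each of WT hypoxia, hog1 aerobic and hog1 hypoxia, all against WT aerobic RNA. The series asks what role Hog1, the MAP kinase of the high-osmolarity response, has in the regulation of gene expression by oxygen. Median spot signals per array were 1141 to 1840 in Cy3 and 5139 to 13999 in Cy5. Per array, 96.8% to 99.1% of spots in Cy3 and 97.1% to 99.9% in Cy5 were well above background. Log2 ratios of the replicates correlated across genes at r = 0.873 in WT hypoxia, 0.41 in hog1 aerobic and 0.824 in hog1 hypoxia, and genes are not independent replicates.

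HOG1 and LEU2 separated the strains as the labels give them. On the 4 mutant arrays the log2 ratio of the deleted gene, HOG1 (YLR113W), was between -6.72 and -6.38, and that of LEU2 (YCL018W), the marker in its place, between 5.64 and 7.12. On the 2 WT hypoxia arrays the ratio of HOG1 was -0.07 and -0.12, and that of LEU2 was -0.14 on both. URA3 did not pass the threshold in any comparison (log2 -0.13 in hog1 aerobic against WT aerobic). HIS3 was not well above background on any array and was not tested. LYS2 is given with the WT comparison.

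WT hypoxia against WT aerobic shows how transcripts of WT cells differed after 5 h under nitrogen, with dilution and added culture time part of the difference. The sterol-related gene HES1 (YOR237W), an oxysterol-binding protein gene, rose 129-fold (log2 7.01 ± 0.24, n = 2 arrays, adjusted p = 9.88e-05). The hypoxic translation factor gene ANB1 (YJR047C) rose 66.5-fold (log2 6.06 ± 0.15, adjusted p = 6.44e-05). The heme synthesis gene HEM13 (YDR044W) rose 45.7-fold (5.52 ± 0.17, adjusted p = 7.43e-05). The gene of the main cytochrome c, CYC1 (YJR048W), fell 32.9-fold (-5.04 ± 0.21, adjusted p = 0.000131). NDE1 (YMR145C), a mitochondrial NADH dehydrogenase, fell 28.4-fold (-4.83 ± 0.14, adjusted p = 6.46e-05). The 10 largest rises also held TIR1 (log2 6.83 ± 0.53), PBI1 (6.70 ± 0.16), TIR4 (5.54), DAN1 (5.40), IZH4 (5.09), SET4 (4.92) and FHN1 (4.76). The 10 largest falls also held ZEO1 (-4.77 ± 0.16), the acyl-CoA synthetase FAA1 (-4.63 ± 0.13), FRE1 (-4.43), FET3 (-3.87), ERG5 (-3.80), YLR108C (-3.65), HXT4 (-3.50 ± 0.62) and the flavohemoglobin YHB1 (-3.47). HXT4 was no longer called without WT hypoxia replicate 1 (log2 -2.61, adjusted p = 0.0825).

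DAN/TIR, PAU, sterol uptake and hypoxic genes were called upward as lists in WT hypoxia. All 8 genes of the DAN/TIR cell wall mannoproteins rose (8 adjusted over the list alone), with a median log2 of 4.37 (camera adjusted p = 1.76e-06). All 24 seripauperin (PAU) genes rose (24 adjusted over the list alone), with a median of 3.99 (adjusted p = 1.76e-17). PAU14 reached 4.18 ± 0.21 and PAU3 4.17 ± 0.23, with the caution that PAU probes may read each other's transcripts. Of 9 genes for sterol uptake, esterification and their regulators, 6 rose and 1 fell (the same counts adjusted over the list alone; median 1.80, adjusted p = 0.00974). They include the sterol transporters AUS1 (4.33 ± 0.21) and PDR11 (2.91 ± 0.19) and the regulator UPC2 (3.09 ± 0.18), while the esterification gene ARE2 fell (-2.37 ± 0.10). Of 10 genes on the list of hypoxic genes repressed in air, 7 rose and 2 fell (same counts over the list alone, median 2.30, camera adjusted p = 0.0191). The list also holds ROX1 and MOT3, which are repressors of hypoxic genes, and CPR1, and the 2 falls were among these. Those that rose include the fatty acid desaturase OLE1 (4.71 ± 0.26) and the ADP/ATP carrier AAC3 (3.27 ± 0.26). None of these lists was called with an estimated correlation (adjusted p = 0.496 for each of them). Ergosterol synthesis genes went both ways: 9 of 25 rose (10 adjusted over the list alone) and 5 fell (5), as with HMG2 (1.94 ± 0.12) and HMG1 (-2.64 ± 0.10), both HMG-CoA reductases. That list was not called (median 0.15 but mean -0.01, adjusted p = 0.537).

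Among the lists called downward in WT hypoxia were the respiratory chain, ATP synthase, the iron regulon, ribosomal proteins and ribosome biogenesis. Of 21 respiratory chain genes, 19 fell and none rose (19 adjusted over the list alone; median -1.67, adjusted p = 1.13e-10). The list holds genes of complexes III and IV and cytochrome c, and also CYB2, NDI1 and NDE1. CYT1 was at -3.44 ± 0.12 and COX5A at -3.24 ± 0.22. Of 21 genes of the iron regulon of Aft1, 9 fell (11 adjusted over the list alone; median -0.77, adjusted p = 1.21e-05). Among them were the ferroxidase FET3, the ferric reductase FRE1, HMX1 (-3.44 ± 0.15) and CCC2 (-2.78 ± 0.14). Of 138 cytosolic ribosomal protein genes, 102 fell (112 fell and 1 rose adjusted over the list alone). Their median was -0.60 (adjusted p = 1.03e-17). Of 35 ribosome biogenesis genes, 29 fell (29; median -1.23, adjusted p = 4.75e-12), with DBP2 at -2.30 ± 0.19 and NSR1 at -1.62 ± 0.11. Each of these 4 lists had an adjusted p = 0.496 with an estimated correlation. Of 14 mitochondrial ATP synthase genes, 4 fell (7 adjusted over the list alone; median -0.35, adjusted p = 0.0191, and 0.575 as the adjusted p with an estimated correlation), but the list was not called without WT hypoxia replicate 2 (median -0.21, adjusted p = 0.201) or with median centring (-0.27, adjusted p = 0.0741).

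General stress, osmostress, glycolysis, tricarboxylic acid cycle and leucine synthesis genes were also called upward as lists. Of 21 general stress genes of Msn2 and Msn4, 11 rose (14 adjusted over the list alone; median 1.37, adjusted p = 3.94e-05). Glycogen phosphorylase GPH1 was at 3.89 ± 0.44 and HSP26 at 3.25 ± 0.45. Of 18 osmostress genes dependent on Hog1, 12 rose and none fell (12 and 1 adjusted over the list alone; median 1.43, adjusted p = 0.000508). The heat shock gene HSP12 was at 3.98 ± 0.29. The glycerol synthesis gene GPD1 rose (2.16 ± 0.34, adjusted p = 0.00536), a call lost without WT hypoxia replicate 2 (1.96, adjusted p = 0.057). Of 21 glycolysis and fermentation genes, 11 rose (15 adjusted over the list alone; median 0.69, adjusted p = 0.000216), with HXK1 at 3.67 ± 0.48. Of 15 tricarboxylic acid cycle genes, 8 rose (9; median 0.58, or 0.33 without WT hypoxia replicate 1, adjusted p = 0.00107). LSC2, a succinyl-CoA ligase subunit, was at 1.92 ± 0.10. Of 11 genes of leucine and branched-chain amino acid synthesis, 7 rose and 2 fell (same over the list alone; median 0.75, adjusted p = 0.0263). Among them LEU1 rose (1.80 ± 0.11), with LEU9 among those that fell (-1.48 ± 0.15). With an estimated correlation the adjusted p was 0.496 for each of these lists, apart from glycolysis (adjusted p = 0.53).

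Heme synthesis (3 of 7 rose, 3 adjusted over the list alone; median 0.25, or 0.43 without WT hypoxia replicate 1, adjusted p = 0.0168), led by HEM14 at 2.52 ± 0.10, was called upward. So was fatty acid oxidation (7 of 14 rose and 2 fell, 9 and 2 over the list alone; median 0.37, adjusted p = 0.0263). Pheromone response (6 of 23 fell and 1 rose, same over the list alone; median -0.34, adjusted p = 0.0174) and filamentous growth (5 of 11 fell, 5 over the list alone; median -0.57, adjusted p = 0.0238) were called downward, with SST2 at -1.21 ± 0.11 and TEC1 at -1.15 ± 0.13. With an estimated correlation their adjusted p values were 0.496, 0.508, 0.575 and 0.496. Without WT hypoxia replicate 2, fatty acid oxidation (0.39, adjusted p = 0.0717) and pheromone response (-0.26, adjusted p = 0.0601) were not called, nor was fatty acid oxidation with median centring (0.37, adjusted p = 0.144). Heme synthesis was not called with the block and Feature Extraction log ratios (0.18, adjusted p = 0.0676).

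Lists not called in WT were cell wall integrity (8 of 20 rose and 3 fell, 9 and 3 adjusted over the list alone; adjusted p = 0.076), oxidative stress defence (3 of 20 rose and 6 fell, same over the list alone; 0.392), NAD synthesis (3 of 6 rose, 3 over the list alone; 0.149), hexose transporters (2 of 16 rose and 3 fell, 2 and 2 over the list alone; 0.667), meiosis (3 of 15 rose and 5 fell, same over the list alone; 0.604), a-cell genes (1 of 6 fell, 0 over the list alone; 0.232) and alpha-cell genes (0 of 4; 0.995). Median and mean differed in sign for hexose transporters (median 0.20, mean -0.19, and a median of -0.29 with median centring) and for oxidative stress defence (median 0.02, mean -0.20, and a median of -0.01 with the Feature Extraction log ratios). Single members past the threshold were HXT5 (1.73 ± 0.18), the glucan synthase GSC2 (3.89 ± 0.27), CWP1 (-2.12 ± 0.14), the peroxiredoxin TSA2 (4.74 ± 0.30), SOD2 (-2.36 ± 0.11), BNA6 (1.35 ± 0.11), SPO13 (0.92 ± 0.10) and BAR1 (-0.80 ± 0.20). BAR1 was not called without WT hypoxia replicate 1 (-1.10, adjusted p = 0.0502) or 2 (-0.50, adjusted p = 0.22), or without either hog1 aerobic array (-0.80, adjusted p = 0.055). LYS2 rose (0.50 ± 0.10, adjusted p = 0.0133), a call lost without WT hypoxia replicate 1 (adjusted p = 0.11) or 2 (adjusted p = 0.0885).

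In all, 2532 of 6239 genes passed the threshold (1317 rose and 1215 fell), and 783 of them changed at least 2-fold. With the replicate block 3515 passed, 1846 rising and 1669 falling, and the block also called the cell wall integrity list (adjusted p = 0.0347, adjusted p = 0.592 with an estimated correlation). These blocked results leave out the error of the mean WT aerobic reference, so the count may be too high. The count without the block treats the shared deviation of the reference as independent between arrays and may be too high too. The count was 959 without WT hypoxia replicate 1, 1258 without replicate 2 and 1631 with scale normalization between arrays. WT hypoxia against hog1 aerobic, with both RNAs in Cy5 and the same WT hypoxia arrays, called 1562 genes.

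**Figure D1:**
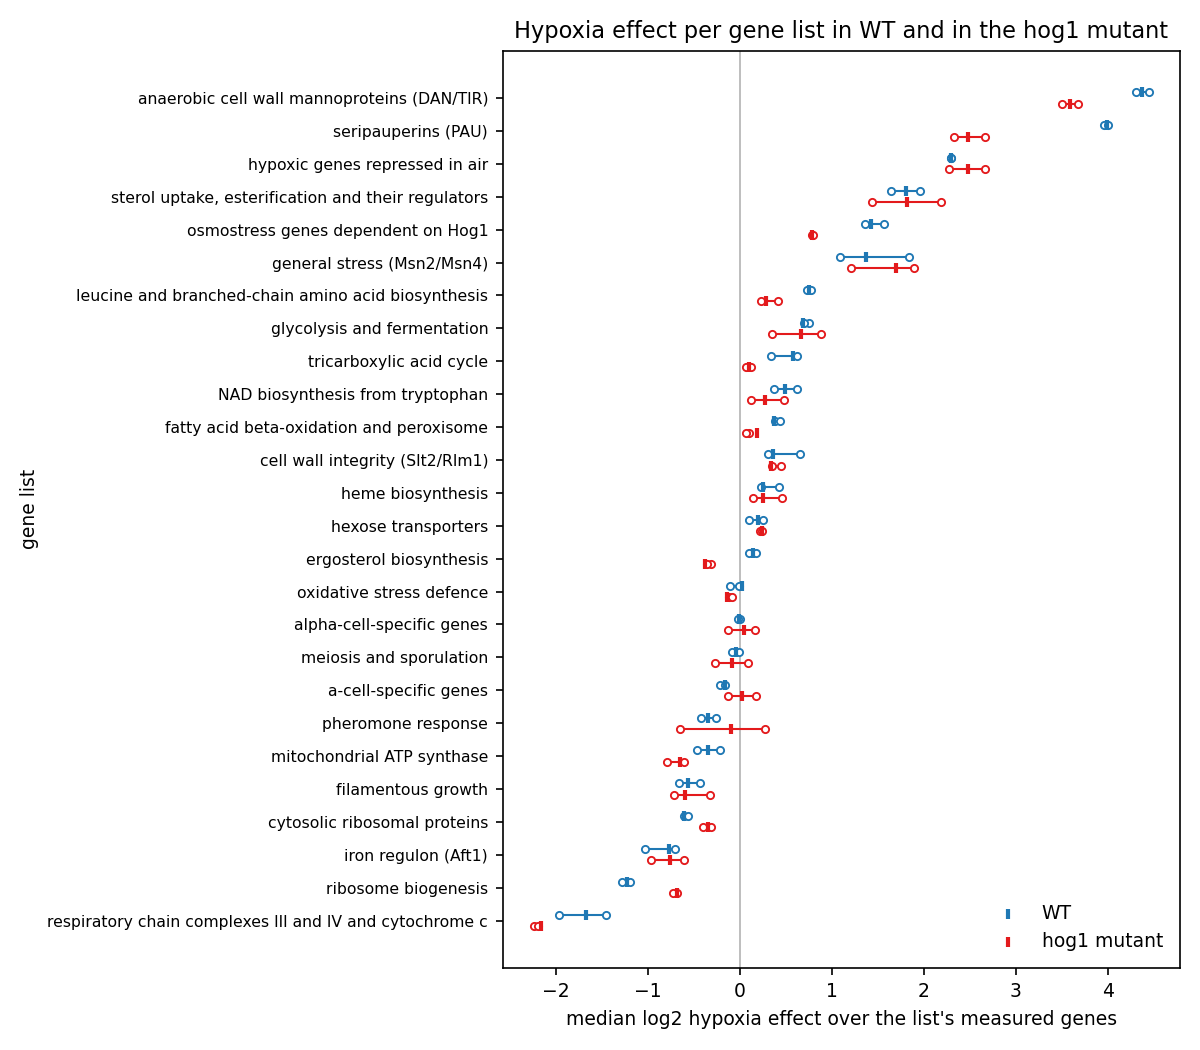
Median log2 hypoxia effect over the measured genes of each of the 26 lists (x axis), in WT (blue) and in the hog1 mutant (red). Open circles are the median in each replicate and the bar is the median of the effects averaged over both, which can lie outside the circles. In both strains DAN/TIR genes lie highest (4.37 and 3.59) and respiratory chain genes lowest (-1.67 and -2.17).

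The comparison of hog1 hypoxia with hog1 aerobic shows the same change of culture, oxygen and time together, in cells without Hog1. Many of the large changes seen in WT were also seen here: HES1 rose 149-fold (log2 7.22 ± 0.35, n = 2 arrays per group, adjusted p = 0.000519), ANB1 96.2-fold (6.59 ± 0.21, adjusted p = 0.00037) and HEM13 30.1-fold (4.91 ± 0.25, adjusted p = 0.000571). CYC1 fell 77.8-fold (-6.28 ± 0.30, adjusted p = 0.000519) and the ferroxidase FET3 (YMR058W) 23.9-fold (-4.58 ± 0.24, adjusted p = 0.000648). The 10 largest rises also held TIR1 (6.14 ± 0.75), DAN1 (6.03), PBI1 (5.83), TIR4 (5.54), IZH4 (5.49), SET4 (5.12) and YGL039W (4.67). The 10 largest falls also held NDE1 (-5.45 ± 0.19), ERG5 (-4.41), YHB1 (-4.37), CYT1 (-4.28), FAA1 (-4.25), FRE1 (-4.01 ± 0.50), COX4 (-3.98) and COX5A (-3.91). HXT4, among the 10 largest falls in WT, was not called here. TIR1 (5.66, adjusted p = 0.0724) and FRE1 (-4.26, adjusted p = 0.0688) were not called without hog1 aerobic replicate 1, nor was FRE1 without replicate 2 (-3.77, adjusted p = 0.0675).

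Lists called upward in the mutant were DAN/TIR, PAU, sterol uptake, hypoxic, general stress, osmostress and glycolysis genes. Of 8 DAN/TIR genes 7 rose (7 adjusted over the list alone; median 3.59, adjusted p = 1.39e-07), and of 24 PAU genes 23 rose (24; median 2.49, adjusted p = 3.19e-18), with PAU18 at 2.83 ± 0.26. Sterol uptake genes rose in 5 of 9 cases and fell in 1 (same over the list alone; median 1.81, adjusted p = 0.00425), with AUS1 at 4.41 ± 0.30. Genes on the list of hypoxic genes rose in 6 of 10 cases and fell in 2 (7 and 2, median 2.49, camera adjusted p = 0.00448). The falls were again among ROX1, MOT3 and CPR1, and OLE1 was at 3.84 ± 0.37. Each of these lists had an adjusted p = 0.46 with an estimated correlation. General stress genes rose in 6 of 21 cases (7; median 1.70, adjusted p = 8.68e-06, adjusted p = 0.479 with an estimated correlation). Their median was 1.11 without hog1 aerobic replicate 1 and 0.76 without hog1 hypoxia replicate 2. Osmostress genes rose in 7 of 18 cases and fell in 1 (9 and 1; median 0.78, adjusted p = 0.00165, adjusted p = 0.46 with an estimated correlation). Glycolysis genes rose in 2 of 21 cases (2; median 0.67, adjusted p = 0.00055, adjusted p = 0.648 with an estimated correlation). The glycolysis median was 0.29 without hog1 aerobic replicate 1 and 1.04 without replicate 2. Median centring ended the glycolysis call (median 0.32, adjusted p = 0.188), and scale normalization gave a glycolysis median of 0.39.

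Respiratory chain genes fell in 18 of 21 cases (19 adjusted over the list alone; median -2.17, adjusted p = 1.29e-17). ATP synthase genes fell in 6 of 14 cases (11; median -0.65, adjusted p = 1.54e-05). Ergosterol synthesis genes fell in 7 of 25 cases and rose in 1 (7 and 2; median -0.38, adjusted p = 0.00055). HMG1 was at -3.19 ± 0.14 and HMG2 at 1.88 ± 0.18. Iron regulon genes fell in 6 of 21 cases (9; adjusted p = 1.85e-06), with HMX1 at -3.88 ± 0.21. The iron median of -0.75 was -1.37 and -0.32 without hog1 aerobic replicates 1 and 2, -1.16 without hog1 hypoxia replicate 2, and -0.25 with scale normalization. Ribosomal protein genes fell in 8 of 138 cases (0 adjusted over the list alone; median -0.35, or -0.64 with median centring, adjusted p = 9.15e-10). Ribosome biogenesis genes fell in 15 of 35 cases (17; median -0.69, or -0.46 without hog1 hypoxia replicate 2, adjusted p = 6.54e-09). Filamentous growth genes fell in 3 of 11 cases (4; median -0.59, adjusted p = 0.00624), a call lost without hog1 aerobic replicate 2 (-0.42, adjusted p = 0.053). With an estimated correlation the adjusted p was 0.46 for each of these 7 lists.

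Lists not called in the mutant were heme synthesis (2 of 7 rose, 2 over the list alone; adjusted p = 0.0585), oxidative stress defence (2 of 20 rose and 5 fell, 3 and 5 over the list alone; 0.166), cell wall integrity (2 of 20 rose and 3 fell, 6 and 3 over the list alone; 0.261), the tricarboxylic acid cycle (1 of 15 rose, 1 over the list alone; 0.243) and leucine synthesis (1 of 11 rose and 1 fell, same over the list alone; 0.196). So were NAD synthesis (1 of 6 rose, 3 over the list alone; 0.284), pheromone response (1 of 23 fell, 1 over the list alone; 0.19), fatty acid oxidation (1 of 14 fell, 0 over the list alone; 0.368) and meiosis (2 of 15 rose, 2 over the list alone; 0.82). Hexose transporters (0.24), a-cell genes (0.82) and alpha-cell genes (0.901) were not called either and had 0 members past the threshold.

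In the mutant 815 of 6239 genes passed the threshold (477 rose and 338 fell), 461 of them at least 2-fold. With the replicate block 1926 passed (1113 rose and 813 fell). Of the 477 that rose, 467 also rose in WT (97.9%, where 101 would be shared by chance). Of the 338 that fell, 322 also fell in WT (95.3%, where 66 would be shared by chance). No gene was called in opposite directions. Across genes, which are not independent replicates, the effects in the 2 strains correlated at Pearson r = 0.9244 and Spearman rho = 0.8785. In 100 simulations without any effect the mean r was -0.0033, with the highest at 0.038. Those simulations drew genes and arrays as independent, so an r near 0 was built in and is no test of the correlation. The lower count in the mutant is no test of a weaker response, since this contrast recovered 18.2% of changes of log2 1 on simulated data, and 69.6% for WT. Without an array the count was 130 (hog1 aerobic replicate 1), 203 (hog1 aerobic replicate 2), 195 (hog1 hypoxia replicate 2), 438 (hog1 hypoxia replicate 1) or 503 (either WT hypoxia array). With scale normalization it was 416. Of the 78 genes named and called here, 35 stayed called without any single array.

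**Figure D2:**
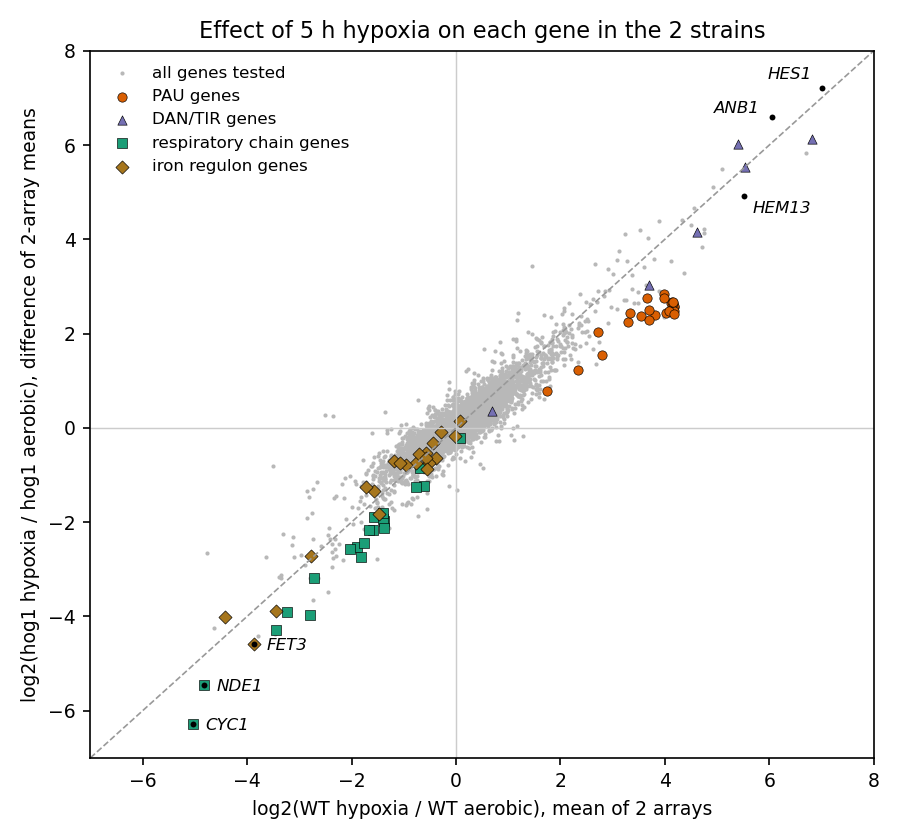
Log2 effect of hypoxia in WT (x axis) and in the hog1 mutant (y axis) for each of the 6239 genes, with the members of 4 lists in colour and the dashed line where both effects are equal. The points follow the line (Pearson r = 0.9244 across genes), and the 24 PAU genes, with medians of 3.99 in WT and 2.49 in the mutant, lie below it.

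The comparison of hog1 aerobic with WT aerobic shows what the strains differed in before hypoxia. Apart from HOG1 (log2 -6.55 ± 0.11, n = 2 arrays, adjusted p = 2.24e-05) and LEU2 (6.07 ± 0.20, adjusted p = 0.000489), 3 genes passed the threshold, all lower in the mutant. LEU1 (YGL009C), an isomerase of leucine synthesis, was 7.94-fold lower (-2.99 ± 0.11, adjusted p = 0.000489). BAT1 (YHR208W), the mitochondrial branched-chain aminotransferase, was 4.33-fold lower (-2.11 ± 0.09, adjusted p = 0.000857). CWP1 (YKL096W), a cell wall mannoprotein, was 5.42-fold lower (-2.44 ± 0.14, adjusted p = 0.00411). BAT1 (adjusted p = 0.0636 and 0.0558) and CWP1 (0.116 and 0.0558) were not called without hog1 aerobic replicate 1 or 2. Their log2 values were then between -2.64 and -2.11.

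With the replicate block, 289 genes passed in air (174 higher and 115 lower in the mutant), and 44 of them differed at least 2-fold. Since the blocked fit leaves out the error of the mean WT aerobic reference, these calls may be too many. The standard errors of the 9 genes given here are those of the blocked fit and can be too small for the same reason. The lower ones include the mitochondrial oxaloacetate carrier OAC1 (-2.03 ± 0.20, blocked adjusted p = 0.0058), the glutamate dehydrogenase GDH1 (-1.61 ± 0.18, blocked adjusted p = 0.00938), and GRE2 (-1.41 ± 0.14, blocked adjusted p = 0.0058). Another is the ferric reductase FRE4 (-1.14 ± 0.09, blocked adjusted p = 0.0035). The higher ones include the respiratory genes CYC1 (1.20 ± 0.10, blocked adjusted p = 0.00421), COX5A (1.15 ± 0.09, blocked adjusted p = 0.00327) and QCR9 (1.09 ± 0.10, blocked adjusted p = 0.0054). Others are the pheromone-regulated PRM2 (1.24 ± 0.23, blocked adjusted p = 0.0347) and the aquaporin AQY2 (1.10 ± 0.14, blocked adjusted p = 0.0127). Without the block, the adjusted p of these 9 genes was between 0.126 and 0.161.

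As lists, respiratory chain genes were higher in the mutant in air (median log2 0.65, 20 of 21 above 0; 14 of 21 past the threshold adjusted over the list alone, 0 over all genes; adjusted p = 2.22e-11, adjusted p = 0.697 with an estimated correlation). ATP synthase genes were also higher (median 0.44, or 0.21 without hog1 aerobic replicate 1; 6 of 14 over the list alone, 0 over all; adjusted p = 8.32e-05, adjusted p = 0.715 with an estimated correlation). So were pheromone response genes (median 0.52, or 0.28 without hog1 aerobic replicate 2; 1 higher and 1 lower of 23 over the list alone, 0 over all; adjusted p = 7.78e-05, adjusted p = 0.715 with an estimated correlation). The a-cell genes (median 0.33, 0 of 6 either way, adjusted p = 0.00411) and ergosterol genes (0.15, 1 of 25 over the list alone and 0 over all, adjusted p = 0.00704) were higher too, each with an adjusted p = 0.697 with an estimated correlation. With median centring the medians of these a-cell and ergosterol lists were 0.71 and 0.69. Alpha-cell genes (0.32, 2 of 4 over the list alone and 0 over all, adjusted p = 0.0083, adjusted p = 0.697 with an estimated correlation) turned to -0.21 with median centring. Scale normalization enlarged the median of each of the 12 lists called in air, among them respiratory chain (1.02), ATP synthase (0.70), ergosterol (0.26), ribosomal protein (0.34), leucine (-0.48), iron (-0.69), osmostress (-0.28) and ribosome biogenesis genes (-0.18).

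Leucine and branched-chain synthesis genes were lower in the mutant (median -0.31; 2 of 11 lower over all genes, 6 lower and 1 higher adjusted over the list alone; adjusted p = 4.74e-05, adjusted p = 0.697 with an estimated correlation), but the median turned to 0.18 with median centring. The median of the iron regulon was -0.39 (1 of 21 lower over the list alone, 0 over all; adjusted p = 0.0135, adjusted p = 0.747 with an estimated correlation), but 0.16 without hog1 aerobic replicate 1 (adjusted p = 0.391), -0.71 without replicate 2 and -0.22 with median centring (adjusted p = 0.291). Cell wall integrity (-0.19; 1 of 20 over all, 4 over the list alone; adjusted p = 0.00704) and osmostress genes (-0.16; 1 of 18 over the list alone, 0 over all; adjusted p = 0.0227), each with an adjusted p = 0.715 with an estimated correlation, had medians of 0.04 (adjusted p = 0.314) and -0.01 (adjusted p = 0.498) without hog1 aerobic replicate 1. Without replicate 2 these were -0.33 and -0.38, and neither list was called with median centring (-0.02, adjusted p = 0.388, and -0.40, adjusted p = 0.0934). Ribosomal protein genes (median 0.21; 34 of 138 higher over the list alone, 0 over all; adjusted p = 6.82e-10, adjusted p = 0.715 with an estimated correlation) had medians of 0.07 (adjusted p = 0.0709) and 0.35 without hog1 aerobic replicate 1 and 2, and 1.02 with median centring. Ribosome biogenesis genes (-0.12, 0 of 35 either way; adjusted p = 0.0168, adjusted p = 0.747 with an estimated correlation) had medians of -0.36 and 0.02 (adjusted p = 0.871) without replicate 1 and 2. With median centring they were called in the opposite direction (0.13, adjusted p = 0.0246), and with the block and Feature Extraction log ratios they were not called (-0.11, adjusted p = 0.0536).

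Not called in air were sterol uptake (adjusted p = 0.99), DAN/TIR (0.671), PAU (0.21), hypoxic genes (0.934), the tricarboxylic acid cycle (0.0669), glycolysis (0.151), hexose transporters (0.47), general stress (0.0882), filamentous growth (0.671), heme synthesis (0.449), oxidative stress defence (0.161), fatty acid oxidation (0.151), NAD synthesis (0.0504) and meiosis (0.353). Over all genes, none of their members passed the threshold, and adjusted over the list alone 3 NAD synthesis genes were higher and 1 glycolysis gene lower. With median centring, medians of these lists moved from 0.11 to 1.16 for glycolysis, from -0.16 to -0.53 for hexose transporters and from 0.18 to 0.40 for the tricarboxylic acid cycle. The replicate block also called general stress (adjusted p = 0.00259) and NAD synthesis (0.041), each with an adjusted p = 0.649 with an estimated correlation. The count of 5 genes was 1251 with median centring and 632 with scale normalization, and 3 without either hog1 aerobic array. At an unadjusted p under 0.05, 1042 genes passed, where chance gives 312.

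**Figure D3:**
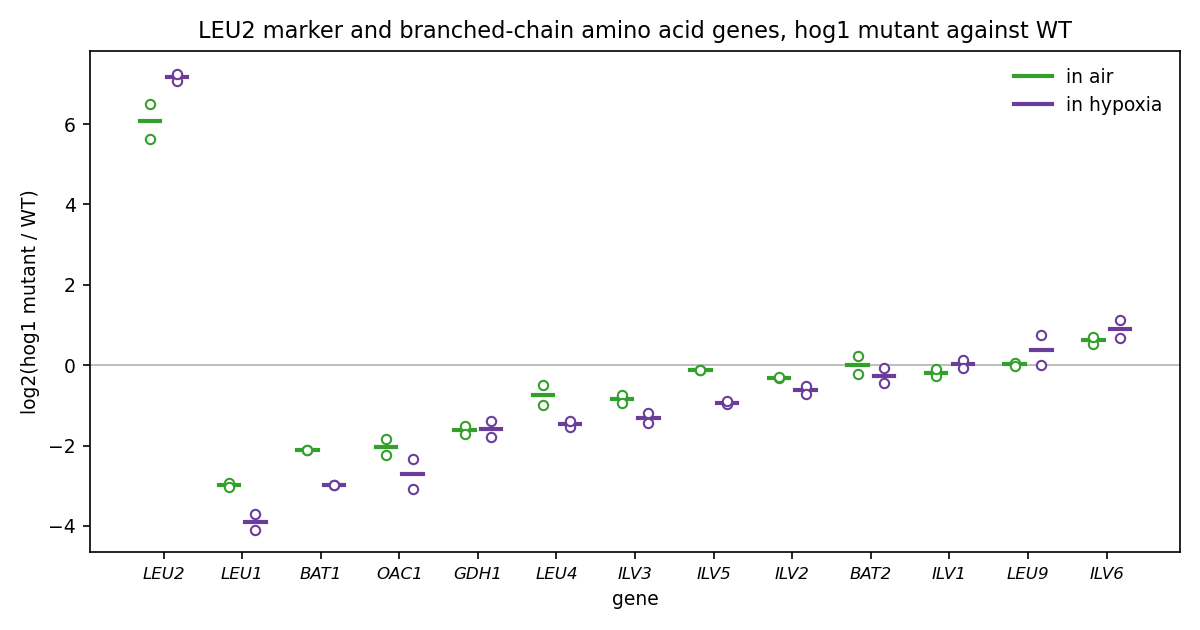
Log2 ratio of the hog1 mutant over WT (y axis) for the LEU2 marker and 12 genes of branched-chain amino acid metabolism or known Leu3 targets, in air (green) and in hypoxia (purple). Circles are the 2 replicates (in hypoxia, the differences of same-numbered arrays) and bars their means. LEU2 lies at 6.07 and 7.17, LEU1 at -2.99 and -3.89 and BAT1 at -2.11 and -2.99, while ILV6 lies at 0.62 and 0.90.

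The comparison of hog1 hypoxia with WT hypoxia shows what the strains differed in after 5 h of hypoxia. Besides LEU2 (log2 7.17 ± 0.28, n = 2 arrays per group, adjusted p = 0.00086) and HOG1 (-6.46 ± 0.16, adjusted p = 0.000177), LEU1 was 14.8-fold lower in the mutant (-3.89 ± 0.15, adjusted p = 0.00086). BAT1 was 7.94-fold lower (-2.99 ± 0.12, adjusted p = 0.00086). These 4 genes were called without any single array too, but with scale normalization 1 gene was called. With the replicate block, 148 genes passed (71 higher and 77 lower in the mutant), 76 of them at least 2-fold. The standard errors of the genes named next are those of the blocked fit. The lower ones include OAC1 (-2.71 ± 0.29, blocked adjusted p = 0.0143), GRE2 (-2.10 ± 0.20, blocked adjusted p = 0.00894), the cell wall gene SED1 (-1.77 ± 0.16, blocked adjusted p = 0.00854) and the mitochondrial carrier DIC1 (-1.72 ± 0.19, blocked adjusted p = 0.0147). The higher ones include ASG7 (2.13 ± 0.33, blocked adjusted p = 0.0321), PRM2 (1.95 ± 0.32, blocked adjusted p = 0.0372), ZEO1 (1.82, blocked adjusted p = 0.0143) and the acid phosphatase PHO3 (1.59, blocked adjusted p = 0.00854). Without the block their adjusted p values were between 0.0533 and 0.245.

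Lists with lower values in the mutant in hypoxia were led by the PAU genes: all 24 were below 0 (24 past the threshold adjusted over the list alone, 0 over all genes, 22 with the replicate block), with PAU3 at -1.74 ± 0.32. Their median was -1.28 (adjusted p = 5.47e-22, adjusted p = 0.374 with an estimated correlation). The DAN/TIR genes, which share 2 members with them, had a median of -0.55 (1 of 8 over the list alone, 0 over all; adjusted p = 0.00221, adjusted p = 0.568 with an estimated correlation). It was between -0.82 without hog1 hypoxia replicate 2 and -0.31 without hog1 hypoxia replicate 1 or WT hypoxia replicate 2. Osmostress genes had a median of -0.82 (5 of 18 over the list alone, 0 over all; adjusted p = 1.13e-06, adjusted p = 0.374 with an estimated correlation), or -0.54 without hog1 hypoxia replicate 1. They include the aldehyde dehydrogenase ALD3 (-1.44 ± 0.25) and GPD1 (-1.33 ± 0.47), with standard errors of the fit without the block. Both genes passed with the block (blocked adjusted p = 0.0248 and 0.0291). Leucine synthesis genes had a median of -0.94, or -0.49 with median centring (2 of 11 lower over all, 7 lower and 1 higher over the list alone; adjusted p = 1.13e-06, adjusted p = 0.374 with an estimated correlation). Ergosterol genes were below 0 in 24 of 25 cases (median -0.42, or -0.24 with median centring; 4 over the list alone, 0 over all; adjusted p = 4.89e-09, adjusted p = 0.335 with an estimated correlation). The demethylase ERG11 was at -0.93 ± 0.21. Cell wall integrity genes had a median of -0.34, or -0.56 without hog1 hypoxia replicate 2 (3 of 20 over the list alone, 0 over all; adjusted p = 1.25e-05, adjusted p = 0.449 with an estimated correlation).

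Lists with higher values in the mutant were ribosomal proteins (133 of 138 above 0, median 0.47, or 0.90 with median centring; 42 over the list alone, 0 over all; adjusted p = 5.84e-29, adjusted p = 0.374 with an estimated correlation). RPL19B was at 1.24 ± 0.18. Ribosome biogenesis genes were all above 0 (35 of 35, median 0.32, 0 past the threshold either way; adjusted p = 1.13e-06, adjusted p = 0.452 with an estimated correlation). Their median was 0.16 and 0.50 without hog1 hypoxia replicate 1 and 2. Pheromone response genes (median 0.57, or 0.36 without hog1 hypoxia replicate 1; 7 of 23 over the list alone, 0 over all; adjusted p = 1.38e-06, adjusted p = 0.452 with an estimated correlation) included the kinase FUS3 (1.09 ± 0.20). The a-cell genes had a median of 0.64 (4 of 6 over the list alone, 0 over all; adjusted p = 4e-05, adjusted p = 0.335 with an estimated correlation). The pheromone gene MFA1 was at 1.21 ± 0.24. Alpha-cell genes had a median of 0.40 (1 of 4 over the list alone, 0 over all; adjusted p = 0.0244, adjusted p = 0.374 with an estimated correlation). They were not called without WT hypoxia replicate 1 (adjusted p = 0.0667) or 2 (0.0527) or hog1 hypoxia replicate 2 (0.0503), nor with median centring (0.15, adjusted p = 0.517).

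Another 4 lists were called lower with no member past the threshold either way, each depending on an array. The tricarboxylic acid cycle (median -0.22, adjusted p = 0.0149, adjusted p = 0.612 with an estimated correlation) was not called without WT hypoxia replicate 1 (-0.04, adjusted p = 0.596) or hog1 hypoxia replicate 1 (-0.09, adjusted p = 0.135), and was -0.43 without hog1 hypoxia replicate 2. General stress genes (-0.35, adjusted p = 0.0355, adjusted p = 0.746 with an estimated correlation) had 0.11 without hog1 hypoxia replicate 1 (adjusted p = 0.338), -0.20 without WT hypoxia replicate 2 (adjusted p = 0.228), -0.74 without WT hypoxia replicate 1 and -1.26 without hog1 hypoxia replicate 2. The iron regulon (-0.23, adjusted p = 0.0149, adjusted p = 0.74 with an estimated correlation) and oxidative stress defence (-0.30, adjusted p = 0.016, adjusted p = 0.735 with an estimated correlation) were not called without WT hypoxia replicate 2 (adjusted p = 0.0744 for both, -0.10 and -0.22) or hog1 hypoxia replicate 1 (adjusted p = 0.194 and 0.273, -0.03 and -0.13). Without hog1 hypoxia replicate 2 they were -0.53 and -0.50. With median centring the tricarboxylic acid cycle (-0.16, adjusted p = 0.372), general stress (-0.34, adjusted p = 0.109) and oxidative stress defence (-0.10, adjusted p = 0.523) were not called. Not called were sterol uptake (adjusted p = 0.316), hypoxic genes (0.614), respiratory chain (0.608), ATP synthase (0.598), glycolysis (0.829), hexose transporters (0.589), filamentous growth (0.799), heme synthesis (0.377), fatty acid oxidation (0.28), NAD synthesis (0.589) and meiosis (0.18). None of their members passed the threshold, except for 1 ATP synthase gene that was lower adjusted over the list alone. At an unadjusted p under 0.05, 724 genes passed, where chance gives 312.

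The difference of the hypoxia effect between the strains asks whether the response to hypoxia itself depended on Hog1. No single gene passed the threshold with limma (0 of 6239, smallest adjusted p = 0.993; 268 at an unadjusted p under 0.05, where chance gives 312). With the replicate block 0 passed too (smallest blocked adjusted p = 0.0568; 671 unadjusted). On simulated data this test recovered 1.25% of differences of log2 1 and 68% of those of log2 2. As a list, the PAU genes had the lowest median: the difference was below 0 in 24 of 24 cases and in both replicates. The median log2 was -1.41 (3.99 in WT and 2.49 in the mutant, 24 past the threshold adjusted over the list alone, 0 over all). The camera adjusted p was 2.4e-30, and 0.537 with an estimated correlation. These 24 values are not separate measurements, since 19 of the probes have a near copy among the PAU probes and 7 an identical stretch of 60 bases. Ribosome biogenesis genes had a difference above 0 in 35 of 35 cases (median 0.52, from -1.23 in WT and -0.69 in the mutant; 0.30 without hog1 hypoxia replicate 1, 0.34 without hog1 aerobic replicate 2 and 0.32 with median centring; 0 past the threshold either way; adjusted p = 1.03e-13, adjusted p = 0.537 with an estimated correlation). Respiratory chain genes had a difference below 0 in 21 of 21 cases (median -0.59, from -1.67 in WT and -2.17 in the mutant, or -0.96 with scale normalization; 0 either way; adjusted p = 3.96e-11, adjusted p = 0.537 with an estimated correlation). The strains were close for this list in hypoxia (median strain difference 0.06, not called), while the mutant was higher in air (0.65). The difference thus came mostly from the comparison in air, in which a dye bias stays. Ergosterol genes had a difference below 0 in 23 of 25 cases (median -0.59, or -0.95 with median centring; 11 over the list alone, 0 over all; adjusted p = 1.18e-16, adjusted p = 0.275 with an estimated correlation). In all, camera with the preset correlation called 13 of 26 lists, of which 6 stayed called without any single array. The lists not called were sterol uptake (adjusted p = 0.294), hypoxic genes (0.681), glycolysis (0.357), hexose transporters (0.315), general stress (0.555), filamentous growth (0.896), cell wall integrity (0.129), heme synthesis (0.147), the iron regulon (0.938), oxidative stress defence (0.246), NAD synthesis (0.143), alpha-cell genes (0.896) and meiosis (0.496).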

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

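All tests of explanations given here were chosen only after the result was seen, apart from the brightness test of the pheromone response genes. The lists given here had hypoxia effects that differed between the strains, by camera with the preset correlation on the difference of the effects (hog1 minus WT). None of the 13 was called with an estimated correlation, and their adjusted p values were between 0.275 and 0.708.

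The largest median difference was that of the PAU genes, -1.407 (camera adjusted p = 2.4e-30), with all 24 below 0 in both replicates. The PAU probes are not separate measurements, since 19 have a near copy. The ergosterol synthesis genes had -0.586 (adjusted p = 1.18e-16, 23 of 25 below 0), or -0.95 with median centring. Respiratory chain genes had -0.5906 (adjusted p = 3.96e-11, 21 of 21 below 0), or -0.96 with scale normalization. Their difference came mostly from air, with strain medians of 0.65 in air and 0.06 in hypoxia. For ATP synthase genes these strain medians were 0.44 and 0.06. Ribosome biogenesis genes had 0.5186 (adjusted p = 1.03e-13, 35 of 35 above 0), or 0.30 without hog1 hypoxia replicate 1, 0.34 without hog1 aerobic replicate 2 and 0.32 with median centring. Tricarboxylic acid cycle genes had -0.3911 (adjusted p = 2.75e-05, 14 of 15 below 0), or -0.23 without WT hypoxia replicate 1. Ribosomal protein genes had 0.2894 (adjusted p = 5.9e-12, 108 of 138 above 0), with 0.14 without hog1 aerobic replicate 2, 0.17 without hog1 hypoxia replicate 1 and 0.06 with scale normalization (adjusted p = 0.805). With median centring the ribosomal protein genes were called in the opposite direction (-0.11, adjusted p = 0.0098). These 6 lists were called without any single array.

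The other lists lost their call without at least 1 array. ATP synthase genes had -0.2963 (adjusted p = 0.000333, 13 of 14 below 0), not called without WT hypoxia replicate 1 (-0.20, adjusted p = 0.0564) or hog1 aerobic replicate 1 (-0.16, adjusted p = 0.104), and had -0.59 with scale normalization. Leucine synthesis genes had -0.4704 (adjusted p = 0.001, 8 of 11 below 0, 3 lower adjusted over the list alone and 0 over all genes), with -0.22 without hog1 hypoxia replicate 2 (adjusted p = 0.107), -0.74 without WT hypoxia replicate 2 -0.77 with median centring and 0.21 with scale normalization (adjusted p = 0.217). Osmostress genes had -0.5574 (adjusted p = 0.000691, 12 of 18 below 0). They were not called without hog1 aerobic replicate 2 (-0.16, adjusted p = 0.08) or hog1 hypoxia replicate 1 (-0.24, adjusted p = 0.0734), nor with scale normalization (0.01, adjusted p = 0.5), and had -0.28 and -0.24 without WT hypoxia replicate 1 and 2. DAN/TIR genes had -0.5679 (adjusted p = 0.00855, 6 of 8 below 0, 2 lower adjusted over the list alone and 0 over all genes). They were not called without WT hypoxia replicate 2 (-0.30, adjusted p = 0.113), hog1 aerobic replicate 2 (-0.25, adjusted p = 0.502) or hog1 hypoxia replicate 1 (-0.15, adjusted p = 0.103), had -0.87 without hog1 hypoxia replicate 2, and were not called with scale normalization (-0.30, adjusted p = 0.208) or median centring (-0.54, adjusted p = 0.0507).

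Fatty acid oxidation genes had -0.1992 (adjusted p = 0.00864, 12 of 14 below 0). They were not called without WT hypoxia replicate 2 (-0.13, adjusted p = 0.0822), hog1 aerobic replicate 2 (-0.01, adjusted p = 0.453) or hog1 hypoxia replicate 1 (-0.08, adjusted p = 0.082), nor with median centring (-0.02, adjusted p = 0.946), and had -0.33 and -0.39 without WT hypoxia replicate 1 and hog1 aerobic replicate 1. Pheromone response genes had 0.185 (adjusted p = 0.0177, 19 of 23 above 0). Their median was -0.03 without hog1 aerobic replicate 1 (adjusted p = 0.61), -0.04 without hog1 hypoxia replicate 1 (adjusted p = 0.985), 0.09 without WT hypoxia replicate 2 (adjusted p = 0.192) and between 0.30 and 0.41 without any of the other arrays, and turned to -0.04 with scale normalization (adjusted p = 0.772). The replicate block ended this call (0.19, adjusted p = 0.0543). The a-cell genes had 0.3053 (adjusted p = 0.0244, 5 of 6 above 0). They were not called without WT hypoxia replicate 2 (0.16, adjusted p = 0.093), hog1 aerobic replicate 1 (0.23, adjusted p = 0.218) or hog1 hypoxia replicate 1 (0.16, adjusted p = 0.203), nor with median centring (0.27, adjusted p = 0.234) or scale normalization (-0.03, adjusted p = 0.982). The call was also lost with the Feature Extraction log ratios (0.21, adjusted p = 0.0613) and the series matrix values (0.21, adjusted p = 0.0592).

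PAU genes were lower in the mutant than in WT in hypoxia, with a median log2 of -1.28. Of these genes, 5 have a probe that shares fewer than 48 of 60 bases with any other PAU probe. Their median was -0.932, with values from -1.07 to -0.724, so the lower values were not limited to near-identical probes. Probes were compared with each other and not with the other PAU transcripts. Whether these 5 probes read separate transcripts cannot be told, and a single transcript read by several probes stays open. A smaller response of all strongly induced bright genes, or compressed ratios, was examined with 81 other genes. They lie in the PAU range of induction (log2 1.74 to 4.18) and brightness. Their median was -0.211 (quartiles -0.531 and 0.0139), and 0 of 10000 random lists were as low as the PAU genes. This argues against an equal reduction of all genes in that range. A reduction that grows with induction stays open, since only the range was matched and the PAU median (3.99) lies near its top. The random lists also treat genes as independent, while the PAU genes had an estimated correlation of 0.897. The number of separate transcripts behind the PAU genes, 19 of which have a probe with a near copy, stays open. Loss of Hog1 and the LEU2 marker, which the design holds together, both stay open as untested biological explanations.

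Leucine pathway genes were lower in the mutant in air (list median -0.31, but 0.18 with median centring) and in hypoxia (-0.94). A lower general amino acid control by Gcn4 is argued against by 31 of its targets outside the branched-chain pathway, with a median strain difference in hypoxia of 0.186 (quartiles -0.0394 and 0.45). The LEU2 marker may be the cause. The 7 targets of Leu3, the regulator that answers to an intermediate of leucine synthesis, had a median of -1.61 in air (-2.45 with scale normalization). Each was below 0 in both replicates, and GDH1 among them is outside the list. The 5 list members that are not targets had 0.00339. In hypoxia the medians of targets and other members were -1.58 and 0.0261. Among the other members, ILV3 was at -0.846 in air, lower than the targets ILV2 (-0.308) and ILV5 (-0.121). The targets were chosen after the data were seen and include LEU1, BAT1, OAC1 and GDH1, already found lower. Their low median is therefore no independent support for the marker. Per the labels WT is leu2 and the mutant carries LEU2 in place of HOG1, so the marker and the loss of Hog1 cannot be told apart here.

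Pheromone response genes were higher in the mutant than in WT in hypoxia, with a median log2 of 0.569, or 0.36 without hog1 hypoxia replicate 1. Strains of different mating type are argued against, since alpha-cell genes had a median of 0.405 and a-cell genes of 0.635, both of the same sign and small. A bias of normalization for probes of the same brightness is argued against, since 0 of 10000 random lists matched on brightness had a median as high, the highest being 0.26. Loss of Hog1, which is known to limit cross-talk to the pheromone pathway, and the LEU2 marker stay open and were not tested apart.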

How the results depend on the processing

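The Cy5 channel alone and the combinations of the replicate block with another setting were chosen only after the data were seen. The array count limits precision, not signal: 96.8% to 99.1% of spots in Cy3 and 97.1% to 99.9% in Cy5 were well above background. No background correction, a normexp offset of 10, the Feature Extraction log ratios, no filter, a stricter filter, outlier spots kept, eBayes with trend and robust, and the series matrix values gave 2480 to 2669 genes for WT hypoxia against WT aerobic, 5 for hog1 aerobic against WT aerobic, 644 to 826 for hog1 hypoxia against hog1 aerobic, 4 to 5 for hog1 hypoxia against WT hypoxia and 0 for the difference of the hypoxia effect. Of 245 values of named genes, 240 stayed on their side of the threshold with the Feature Extraction log ratios (5 weaker), 236 with trend and robust, 223 with median centring, 191 with the replicate block (54 stronger) and 189 with scale normalization (38 weaker, 17 stronger). Of 72 list calls, 71 were kept with the replicate block (all but pheromone response in the difference of the hypoxia effect), 66 with scale normalization, 55 with median centring and none with an estimated correlation. Of the 2532 calls in WT hypoxia against WT aerobic, 19 changed sign with median centring. The mean over several probes was not run, since each gene has 1 probe, nor was a block by slide or scan, since there is 1 of each.

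For WT hypoxia against WT aerobic (2532 genes), the count was 1631 with scale normalization, 783 with a 2-fold size threshold, 1562 against hog1 aerobic with both in Cy5, and 959 to 2400 without an array. For hog1 aerobic against WT aerobic (5 genes), it was 1251 with median centring, 632 with scale normalization, 289 with the replicate block, 265 with the block and Feature Extraction log ratios, 1881 with the block and median centring, 2 where 1 sign was required on all 6 arrays, those of hypoxia included (all 5 have 1 sign on both hog1 aerobic arrays), and 3 to 6 without an array. For hog1 hypoxia against hog1 aerobic (815 genes), it was 416 with scale normalization, 1926 with the replicate block, 1882 with the block and Feature Extraction log ratios, 1777 with the block and median centring, 461 with a 2-fold size threshold, 1399 in the Cy5 channel alone, and 130 to 503 without an array. For hog1 hypoxia against WT hypoxia (4 genes), it was 1 with scale normalization, 148 with the replicate block, 110 with the block and Feature Extraction log ratios, 117 with the block and median centring, and 53 in the Cy5 channel alone. A 2-fold threshold lowers counts by construction. Scale normalization sets all arrays to a common spread. The SD of the log2 ratios was 0.348 and 0.356 on the hog1 aerobic arrays and 0.759 to 0.85 on the hypoxia arrays. This scaling therefore enlarges the ratios in air and shrinks those in hypoxia by construction. For the other changes of count the cause was not tested.

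Some values reversed. CWP1 in hog1 hypoxia against hog1 aerobic had a log2 of 0.8998 with scale normalization, against -1.06. In hog1 aerobic against WT aerobic, median centring, with or without the block, gave medians of 0.1264 for ribosome biogenesis, 0.1816 for leucine synthesis and -0.2116 for alpha-cell genes. In the difference of the hypoxia effect it gave -0.1068 for ribosomal proteins, and scale normalization gave -0.04128 for pheromone response and 0.2071 for leucine synthesis. Leaving out an array gave -0.7095 to 0.159 for the iron regulon in hog1 aerobic against WT aerobic, positive without hog1 aerobic replicate 1. It gave -1.264 to 0.1076 for general stress in hog1 hypoxia against WT hypoxia, positive without hog1 hypoxia replicate 1. Scale normalization enlarges the hog1 aerobic ratios and shrinks the hypoxia ratios by construction, which enters the values that it reversed. For the other reversals the cause was not tested.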

Other observations

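The gene groups and pairs given here were chosen only after the data were seen, and the groups were not recomputed without single arrays.

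Phosphate-related genes (targets of Pho4, with the acid phosphatase PHO3) were lower in WT hypoxia than in WT aerobic: 13 of 15 fell and 1 rose (the same counts adjusted over the list alone), with a median log2 of -1.48 (adjusted p = 2.27e-06, adjusted p = 0.639 with an estimated correlation). They include PHM6 (-3.13 ± 0.15), the acid phosphatase PHO5 (-2.84 ± 0.43) and the phosphate transporters PHO89 (-2.81 ± 0.29) and PHO84 (-1.46 ± 0.29). In the mutant 3 of 15 fell (7 adjusted over the list alone), with a median of -0.84, or -0.31 with scale normalization (adjusted p = 0.00024, adjusted p = 0.894 with an estimated correlation). The difference of the effects had a median of 0.81, with 13 of 15 above 0 (adjusted p = 4.2e-09, adjusted p = 0.447 with an estimated correlation). In hog1 aerobic against WT aerobic the median was -0.26 (adjusted p = 0.00598, adjusted p = 0.64 with an estimated correlation) and turned to 0.01 with median centring. In hog1 hypoxia against WT hypoxia it was 0.48 (adjusted p = 0.00277, adjusted p = 0.411 with an estimated correlation).

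Pairs of genes that encode a hypoxic and an aerobic form of the same protein moved apart in both strains, with 1 exception. The translation factor pair ANB1 and HYP2 had log2 hypoxia effects of 6.06 ± 0.15 and -2.45 ± 0.28 in WT, and 6.59 and -3.49 in the mutant. The cytochrome c oxidase pair COX5B and COX5A had 2.65 ± 0.24 and -3.24 ± 0.22 in WT, and 3.47 and -3.91 in the mutant. The ADP/ATP carrier pair AAC3 and PET9 had 3.27 ± 0.26 and -1.51 ± 0.20 in WT, and 3.53 and -2.78 in the mutant, where AAC3 was not called without hog1 aerobic replicate 1 (3.21, adjusted p = 0.0519). The exception was cytochrome c, where the values of CYC7 were -1.03 ± 0.54 in WT (adjusted p = 0.177) and -0.83 in the mutant (adjusted p = 0.511), while CYC1 fell.

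Mitochondrial ribosomal protein genes were lower in the mutant in hypoxia, with a median strain difference of -0.20 and 47 of 56 below 0 (0 past the threshold, adjusted p = 0.000115, adjusted p = 0.411 with an estimated correlation). In WT hypoxia against WT aerobic 7 of 56 rose and 4 fell (6 and 4 adjusted over the list alone) and the list was not called (adjusted p = 0.08). With the replicate block, the hexose transporter genes HXT7 (2.58 ± 0.25), HXT6 (2.46 ± 0.23) and HXT4 (2.32 ± 0.19) were higher in the mutant in hypoxia. Their blocked adjusted p values were 0.00969, 0.00894 and 0.00778, but they did not pass without the block (adjusted p = 0.447, 0.457 and 0.415). The standard errors of the hexose transporter genes given here are those of the blocked fit. Without hog1 hypoxia replicate 2 HXT7 was at 1.26 and HXT6 at 1.18, and without replicate 1 at 3.89 and 3.73. For HXT4 the log2 ratios of WT hypoxia replicates 1 and 2 lay apart, at -4.4 and -2.61. HXT1 went the other way, with a value of -2.87 ± 0.54 that did not pass (blocked adjusted p = 0.05, adjusted p = 0.255 without the block). Probes of these genes may read each other's transcripts.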
